A study of Homo sapiens with 9 samples.

How the data were processed

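The series holds 9 libraries of the A549 lung adenocarcinoma line: 4 TargetSite and 4 RNA libraries of xenografts, 1 of each per mouse, and 1 RNA library of preimplantation cells. Per the labels' protocols, cells were loaded on the 10x Chromium 3' platform with a version 2 or version 3 kit, and target sites were amplified from the same cDNA. Which kit served which mouse is not given in the sources used here.

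The RNA values are raw UMI counts per gene and cell, deposited by the authors as matrices; the submitters' processing notes name Cell Ranger 2.0.1 and the builds hg19 and GRCh38, without saying which library used which. The gene tables of M5k, M30k and the preimplantation library list 33694 Ensembl IDs and those of M10k and M100k 32738. Libraries were joined on the 31232 IDs present in all, which hold 99.5% to 99.7% of the UMIs of each library. The TargetSite tables hold UMI and read counts per target site molecule and the indel at each of 3 cut sites, per the file headers; how the authors aligned, collapsed and assigned molecules to clones is not given in the sources used here. The deposited cell annotation gives the tissue, the clone and the authors' tissue dispersion and tree metastasis rate, each a fraction between 0 and 1 per clone, whose formulas are not given in the sources used here. Tissue codes are the authors'; LL is read as the left lung, and where this reading is wrong the site comparison would be between LL and the rest. In each mouse every tissue code is its own 10x lane, so tissue and lane cannot be separated. A tissue in the rates below is 1 code. For M5k the annotation also merges M1 with M2 and RE with RW as single sites. Relatives in such paired lanes count as lying in another tissue here, except where sites are said to be merged.

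Cells without annotation were left out: 5609 barcodes of M5k, 5171 of M30k, 5677 of M10k, 1484 of M100k and 0 of the preimplantation library. No further filter was set on cells and no doublet caller was run; doublets are treated only as far as the authors' annotation leaves them out. Cells were not used as replicates. Raw counts were summed per library, per mouse and site class (LL, or all other tissues), per clone, or per clone and site class. UMI totals of the site sums ran from 10339839 (M30k, LL) to 269933573 (M5k, other sites), so a gene at 1 CPM had about 10 counts in the smallest sum. Shares have 95% Wilson intervals and a count of 0 has a floor of 3 counts; both cover counting error.

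The tissue-crossing rate was computed from the indels. The distance between 2 cells is the mean over shared cut sites of 0 for the same state, 1 for edited against unedited and 2 for different edits. For each cell the share of its nearest relatives, ties averaged, that lie in another tissue was taken, and averaged over the clone. The expected rate is the chance that 2 cells of the clone lie in different tissues. Clones with at least 50 cells were used, and tissue labels were shuffled 100 times within each clone. Tissue dispersal is 1 minus Cramer's V of the clone's tissue counts against those of all other cells of the mouse, and is close to 1 for small clones whatever their spread. Correlations over clones have two-sided permutation p-values from 100000 resamples, exact under 10 clones, adjusted over a family of 12.

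Genes were tested with edgeR 4.0.16 (TMM normalization, filterByExpr, robust glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The xenograft comparison takes 4 mice against the 1 preimplantation library; the site comparison takes 8 sums of 4 mice with the mouse as a block, since both sums come from the same animal; the clone comparison takes the rate, scaled to 1 SD, as a covariate over 62 clones of M5k with at least 50 cells in both libraries. 28 gene lists with 537 entries were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, with an estimated correlation as an alternative. DESeq2 1.42.0 served as an alternative for normalization and test. The SE of a log2 fold change is its size divided by the root of the quasi-likelihood F statistic. Clone profiles before and after implantation were log2 values of CPM + 10 over the most variable genes above 20 CPM, centred on the mean over clones in M5k and on the whole library before implantation. Coordinates are from GENCODE version 29 on GRCh38, matched by Ensembl ID, and may differ from the build of the counts. Other tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

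The comparisons, the lists, the rule for named genes and 64 alternative settings were fixed before the data were examined, and 36 alternatives were added later. The rule names, per comparison, the 10 largest rises and 10 largest falls among called genes with a mean of at least 20 CPM that moved the same way in every mouse where mice are the replicates, 2 members of each called list (3 for the clone rate) with the smallest adjusted p, and 8 candidate genes; where fewer than 5 genes pass, the 5 with the smallest p are named. In the site comparison, some list members that the rule takes are not printed. HBB, ALB, EGFL7, ESAM, AMBP and APOH are outside that rule and were chosen after their values were seen.

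The gene comparisons and the crossing rate were tested on simulated data first, and the gene list test was not. The changed genes were drawn from those above 20 CPM on average. Recovery of lower genes, such as IL6 at 4.75 CPM in the site comparison, was therefore not measured. Of 100 simulated genes per size, the xenograft comparison recovered 0% at a log2 change of 1 and 16% at 2 (18820 genes fitted, 3 false calls), the site comparison 100% and 98% (15696 genes, 27 false calls), and the clone comparison 100% at slopes of 0.5 and of 1 (8268 genes, 7 false calls). In the site simulation, 27 false calls stood beside 100 and 98 recovered genes. Its recovery cannot be taken as that of real genes of the same size. In the data, CCL20 (34.7 CPM, log2 fold change 1.83) and KRT17 (126 CPM, 1.00) were not called. Few calls in the site comparison therefore do not show that few genes differ between sites. In 7 simulated clones of 512 cells, the crossing rate ranked the clones in the order of their simulated movement (Spearman rho = 1). These clones had the same editing probability, each edit gave a new state and no site was missing. Whether the rate also ranks clones that differ in editing, as those of M5k did (0.574% to 97.7%), was not tested.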

Results

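Cells of A549, a human lung adenocarcinoma line, carried a Cas9 lineage recorder and were grown in immunodeficient mice after transplantation to the left lung. The recorder writes insertions and deletions (indels) at 3 cut sites of each integrated target site. Cells that share indels are close relatives, and cells that share integrations form a clone. For each of 4 mice, named M5k, M30k, M10k and M100k, a TargetSite library and an RNA library were analysed, with 1 RNA library of cells before implantation, 9 libraries in all. Each mouse name stands for 1 animal, so values of single mice have no replicates and the mouse is the replicate where groups are compared. The RNA libraries held 37814 cells in M5k, 17189 in M30k, 2541 in M10k, 5806 in M100k and 8726 before implantation. Their total counts of unique molecular identifiers (UMIs) were 297892107, 236107425, 119416890, 228767919 and 243444036. The median UMI count per cell was 6322 in M5k, 12657 in M30k, 46291 in M10k, 38845.5 in M100k and 26676.5 before implantation. Tissues are given as codes. The code LL is read here as the left lung, because the labels name that lung as the implantation site, and the other codes are printed as they stand.

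Nearly all clones were found in several tissues. The TargetSite tables held 100 clones in 40969 cells of M5k, 4 in 18218 cells of M30k, 13 in 2566 cells of M10k and 31 in 5987 cells of M100k. Of these, 92, 3, 13 and 31 had cells under at least 2 tissue codes. The LL lane held 5.46%, 3.58%, 15.1% and 30.5% of the TargetSite cells of the 4 mice. The largest clone held 27.0% of the cells in M5k, 93.9% in M30k, 33.9% in M10k and 49.8% in M100k. The share of cut sites carrying an indel was 57.1% in M5k (95% Wilson interval 57.0 to 57.2) and 88.3% in M30k (88.2 to 88.5). It was 36.8% in M10k (36.4 to 37.3) and 48.2% in M100k (47.9 to 48.5). These intervals cover counting error only, and the share ranged from 0.574% to 97.7% over the clones of M5k.

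How often lineages moved between tissues was asked with a tissue-crossing rate, the mean share of a cell's nearest relatives that lay in another tissue. Over clones with at least 50 cells, the median rate was 0.288 in M5k (66 clones, range 0 to 0.772) and 0.464 in M30k (4 clones, 0 to 0.701). It was 0.681 in M10k (10 clones, 0.0147 to 0.820) and 0.518 in M100k (14 clones, 0.0536 to 0.697). Were tissue independent of lineage within a clone, the medians would have been 0.661, 0.71, 0.794 and 0.735. The rate lay below that of each of 100 shuffles of the tissue labels in 55 of 62 clones of M5k that had more than 1 tissue. The same held in 3 of 3 such clones of M30k, 5 of 10 of M10k and 9 of 14 of M100k (permutation p = 0.0099 per clone, the smallest the shuffles can give). The median ratio of observed to expected rate was 0.489 in M5k, 0.724 in M30k, 0.933 in M10k and 0.721 in M100k. Of the tested clones, 1 of M5k and 3 of M10k lay above their expected rate. The highest ratio, 3.20, was that of clone 1 of M10k, whose low rate of 0.0147 goes with an expected rate of 0.0046. With 1 animal per name, the mice were not tested against each other. The M5k annotation merges the codes M1 with M2 and RE with RW. With these merged, the rate went from 0.720 to 0.545 in clone 1 and from 0.440 to 0.327 in clone 2. It went from 0.0300 to 0.0105 in clone 3 and from 0.584 to 0.204 in clone 18. Expected rates and shuffles were not computed on merged codes.

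**Figure D1:**
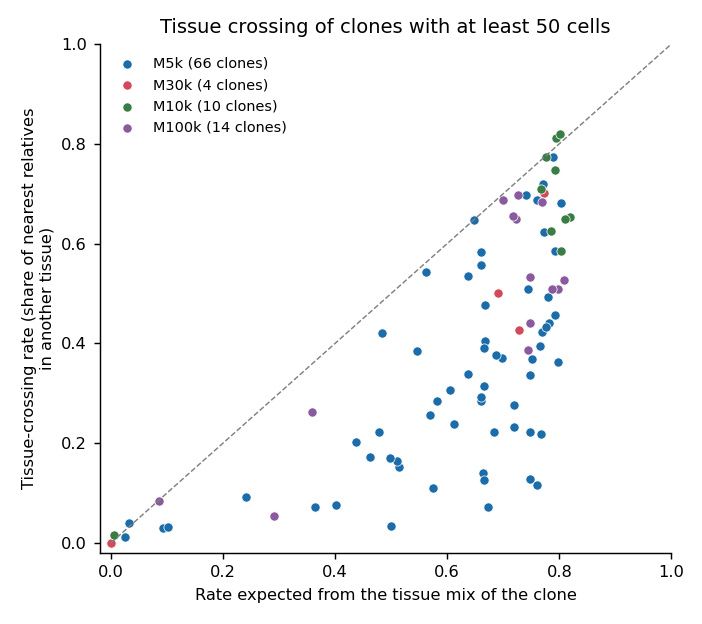
Tissue-crossing rate (y axis, share of nearest relatives in another tissue) against the rate expected from the tissue mix of the clone (x axis), 1 point per clone with at least 50 cells, coloured by mouse, with a dashed line of equality. Most points of M5k lie below the line (median 0.288 against 0.661), and clone 1 of M10k sits near the origin at 0.0147.

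In M5k, cells of the lanes Liv and LL had the largest ratios of observed to expected relatives in their own lane. A low expected share leaves more room for a high ratio, and it was 10.8% in Liv and 17.4% in LL against 55.2% in M2. This ratio was 3.23 in Liv, 2.91 in LL, 2.39 in RW, 1.69 in RE, 1.52 in M1 and 1.29 in M2. Each pair of different lanes had a ratio below 1, and the lowest was 0.352, for LL cells with relatives in Liv. Relatives lay in another tissue for 49.4% in LL (82.6% expected), 65.0% in Liv (89.2% expected), 37.4% in M1 (58.8% expected) and 29.1% in M2 (44.8% expected). In lane NW of M100k the share was 30.2% (71.5% expected). These shares have no replicate error.

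**Figure D2:**
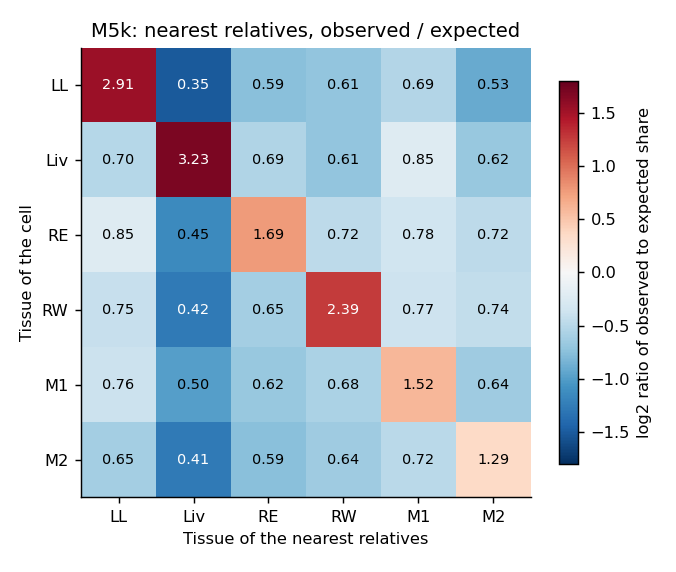
Ratio of observed to expected share of nearest relatives in M5k, by the lane of the cell (vertical axis) and the lane of the relatives (horizontal axis), with colour giving the log2 ratio. The diagonal runs from 1.29 (M2) to 3.23 (Liv), and each other pair of lanes is below 1.

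The rate was set against 4 other clone measures in the 3 mice with at least 6 clones, 12 correlations in all. In M5k the rate correlated with tissue dispersal, the closeness of a clone's tissue mix to that of the whole mouse. Both measures come from the tissue counts of the clone, so part of this is built in. Pearson r was 0.343 (permutation p = 0.00285, adjusted p = 0.00855) and Spearman rho 0.447 (permutation p = 0.00022, adjusted p = 0.00132) over 66 clones. Without the 2 clones farthest from the median dispersal, r was 0.285 (permutation p = 0.0208). In M100k, r with dispersal was 0.825 (permutation p = 0.0013, adjusted p = 0.00585), rho was 0.618 (permutation p = 0.0209, adjusted p = 0.0628), and r without 2 of the 14 clones was 0.723. With the rate divided by its expected value, which takes out the tissue mix, no relation was detected in M5k (62 clones, r = 0.0615, permutation p = 0.647; rho = 0.168, permutation p = 0.189) or in M100k (r = 0.315, permutation p = 0.271; rho = 0.0989, permutation p = 0.74). In M5k no relation with clone size was detected (r = 0.108, permutation p = 0.391, adjusted p = 0.469; rho = 0.0322, permutation p = 0.797), nor with the edited share (r = 0.0598, permutation p = 0.63; rho = 0.103, permutation p = 0.405). Without 2 clones these r were -0.0404 and 0.148. A correlation can miss a relation at 1 end of the range. Clones 16, 18, 25, 50 and 65, with 1.28% to 7.59% of cut sites edited, had observed-to-expected ratios of 0.806 to 0.997. The median ratio in M5k was 0.489. At high editing the ratio went both ways, with 0.941 in clone 53 (92.0% edited) and 0.489 in clone 33 (89.5%). In clones with little editing the rate may thus mostly follow the tissue mix, which was not tested. The authors' deposited tree-based rate correlated with the rate in M5k (54 clones, r = 0.898, rho = 0.935, r = 0.89 without 2), with permutation p = 1e-05 for each, the smallest the resamples can give, and adjusted p = 0.00012. In M100k this r was 0.924 (exact p = 0.00146, adjusted p = 0.00585) and rho 0.881 (exact p = 0.00724) over 8 clones. Without 2 of them r was 0.768 (exact p = 0.0889, 6 clones). In M10k none of the 4 correlations passed (smallest adjusted p = 0.136).

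The 4 xenograft libraries were compared with the preimplantation library, which asks how cells from the animals differed from those before implantation. Growth in the animal cannot be told apart here from recovery of the cells from tissue or from differences between the libraries. Nor can it be told apart from which clones engrafted, as 8.38% of the preimplantation cells were marked as engrafted. The largest called rise was that of a surface antigen. CEACAM5, a cell surface antigen of gut and tumour epithelium (ENSG00000105388; GRCh38 chromosome 19, 41708585 to 41729798), averaged 53.6 ± 33.1 CPM in the xenografts (SD, n = 4 mice; CPM is the count scaled to library size). Before implantation it was at 0.0304 CPM, a ratio of 1764 that rests on 7 counts. The mucin gene MUC16 averaged 25.1 ± 16.5 CPM against 0.0174, from 4 counts. IGFBP1, a secreted binder of insulin-like growth factors (ENSG00000146678; chromosome 7, 45888357 to 45893668), averaged 239 ± 36.1 CPM against 2.50. The antiprotease gene SLPI averaged 359 ± 155 CPM against 6.67, the copper carrier gene CP 161 ± 53.4 against 1.61, and ASS1, of arginine synthesis, 124 ± 29.7 against 1.55. The largest fall was that of the potassium channel gene KCNMA1 (ENSG00000156113; chromosome 10, 76869601 to 77638369), at 1.64 ± 1.29 CPM against 98.4. The adaptor gene AP1M2 fell from 239 to 19.4 ± 8.20 CPM, the cell cycle transcription factor gene MYBL2 from 82.9 to 7.08 ± 3.27, and PSAT1, of serine synthesis, from 92.6 to 11.2 ± 1.72. Each of these genes moved the same way in 4 of 4 mice, which the rule for naming them required. All 4 mice were set against the same preimplantation library.

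The test called 60 genes higher and 60 lower in the xenografts, of 19397 (edgeR, adjusted p under 0.05), and 3799 had an unadjusted p under 0.05. The log2 fold change was 10.76 for CEACAM5 (SE 1.52, adjusted p = 0.0471), 6.78 for ATF3 (SE 0.63, adjusted p = 0.041), 6.58 for IGFBP1 (SE 0.55, adjusted p = 0.041) and -5.90 for KCNMA1 (SE 0.78, adjusted p = 0.0456). Other called rises were FAM83A (7.29), CA9 (6.54) and NR4A3 (6.52). Other called falls were PHF19 (-2.77), NETO2 (-2.32), HMOX1 (-2.19), CENPM (-2.17), BAX (-2.11) and FADS1 (-2.08). The lone preimplantation library was assumed to vary like the mice, and simulated log2 changes of 2 were recovered for 16% of changed genes above 20 CPM. Without M30k, M10k or M100k edgeR called 0 genes (2894, 3448 and 3391 at an unadjusted p under 0.05), and on LL cells alone also 0 (2820).

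**Figure D3:**
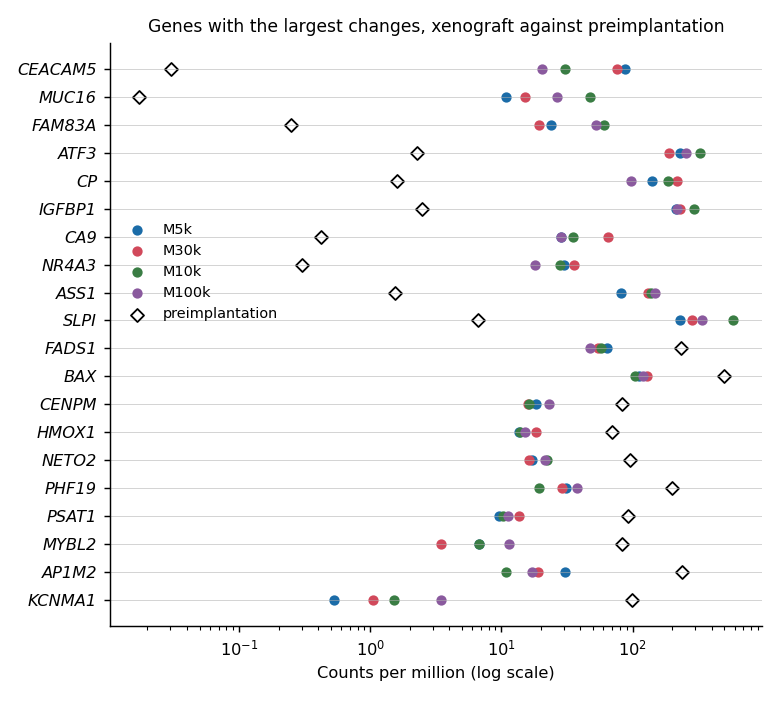
CPM on a log axis of the 20 genes with the largest called changes, 1 coloured point per mouse and a separate marker for the preimplantation library. KCNMA1 lies between 0.53 and 3.48 CPM in the 4 mice against 98.4 before implantation.

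Of 28 gene lists fixed in advance, camera with a preset correlation called 11 higher and 4 lower, and 0 were called with an estimated correlation. In the gastrointestinal lineage list, 2 of 21 genes rose over all genes tested and 15 adjusted over the list alone (adjusted p = 6.63e-09, and adjusted p = 0.37 with an estimated correlation). The 2 were FGB, a fibrinogen chain (5.61), and CDH17, a gut cadherin (3.31). Of NF-kB targets, 19 of 21 had a positive log2 fold change, 0 were called over all genes and 16 rose adjusted over the list alone (adjusted p = 1.61e-08, and adjusted p = 0.383 with an estimated correlation). The complement gene C3 averaged 61.6 CPM against 1.68, and NFKBIA had 2.42. Of 22 hypoxia genes, CA9 rose over all genes and 14 rose adjusted over the list alone, P4HA1 with 2.51 (adjusted p = 4.00e-08, and adjusted p = 0.37 with an estimated correlation). Of 19 immediate early and heat shock genes, ATF3 and NR4A1 (3.11) rose over all genes and 8 rose adjusted over the list alone (adjusted p = 8.9e-07, and adjusted p = 0.37 with an estimated correlation). Interferon-stimulated genes had a median of 3.25, with 25 of 26 positive, 0 called over all genes and 1 adjusted over the list alone (IFI27 7.74, OAS1 3.99; adjusted p = 2.92e-06, and adjusted p = 0.527 with an estimated correlation).

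Epithelial genes had 0 calls over all genes and 7 of 18 rises adjusted over the list alone (SPINT1 3.48, CLDN7 4.59; adjusted p = 0.000189, and adjusted p = 0.37 with an estimated correlation). Invasion and matrix genes had 0 and 4 of 28 (LAMB3 3.48, ITGA6 2.10; adjusted p = 0.00212, and adjusted p = 0.37 with an estimated correlation). Of 10 basal and squamous keratins, 0 were called over all genes, and 5 rose and 1 fell adjusted over the list alone (KRT16 3.67, KRT80 -1.59; adjusted p = 0.00906, and adjusted p = 0.37 with an estimated correlation). Of 14 MHC class I genes, 0 were called either way (HLA-E 1.38, HLA-B 2.53; adjusted p = 0.0227, and adjusted p = 0.627 with an estimated correlation). Alone among the 15 lists, this one also lost its call without M10k and with the 2 mice that share the preimplantation gene table.

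Proliferation lists were lower. G2/M genes had a median of -1.36, with 2 of 53 positive, 0 called over all genes and 5 falls adjusted over the list alone (CENPA -2.94, PSRC1 -3.06; adjusted p = 2.97e-09, and adjusted p = 0.576 with an estimated correlation). S phase genes had a median of -1.13, with 4 of 38 positive, 0 called over all genes and 1 fall adjusted over the list alone (CDCA7 -1.90, GINS2 -2.74; adjusted p = 7.67e-06, and adjusted p = 0.627 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.56, with 0 of 31 called (NDUFS6 -1.23, ATP5G1 -1.21; adjusted p = 0.000911, and adjusted p = 0.539 with an estimated correlation). Cholesterol synthesis genes had a median of -0.66, with 0 called over all genes and 4 of 20 falls adjusted over the list alone (DHCR7 -1.67, MVK -1.59; adjusted p = 0.0128, and adjusted p = 0.377 with an estimated correlation).

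Markers of host cells moved with these groups. The red cell list was called higher, with 0 of 5 called over all genes and 1 adjusted over the list alone (adjusted p = 0.00469, and adjusted p = 0.403 with an estimated correlation). HBB was at 903 CPM in M5k, 275 in M30k, 3.46 in M10k and 35.0 in M100k against 0.260 before implantation. ALAS2 had 0 counts before implantation, and its mean in the mice was about 186-fold or more above a floor of 3 counts in that library, but it was at 6.57 CPM in M5k, 2.68 in M30k, 0.0635 in M10k and 0.365 in M100k. HBA2 had 4.56, and is a near-identical copy of HBA1. The hepatocyte list was called higher, with 0 of 10 called over all genes and 4 adjusted over the list alone (SERPINA1 6.71, TTR 6.20; adjusted p = 0.000122, and adjusted p = 0.383 with an estimated correlation). ALB was at 0.00936 to 0.141 CPM in the mice. The immune, endothelial and fibroblast lists were not called (adjusted p = 0.171, 0.238 and 0.953), though 1 of 3 endothelial genes, ESAM, was called lower over all genes (-4.66, adjusted p = 0.0456). Of 8 candidate metastasis genes, chosen partly from knowledge of the study and so not independent evidence, 0 were called over all genes, and 5 rose and 1 fell adjusted over the list alone. REG4 had 0 counts before implantation and 129 ± 102 CPM in the mice, about 9935-fold or more above the same floor (adjusted p = 0.0818). ID3 had -2.04 (adjusted p = 0.0722), KRT17 9.54 (adjusted p = 0.2), IFI6 5.49 (adjusted p = 0.191), TNNT1 -1.09 (adjusted p = 0.307) and ASPM -1.31 (adjusted p = 0.508).

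Cells outside the LL lane were compared with those in it within each mouse, which asks whether tumour cells at other sites differ from those at the implantation site. The inflammatory cytokine gene IL6 (ENSG00000136244; GRCh38 chromosome 7, 22725884 to 22732002) was higher outside LL in 4 of 4 mice, at 6.99 against 2.52 CPM on average. By lane it was above LL in 14 of 20. In M10k its log2 ratio was -0.88 in M1, -1.12 in M2, -0.24 in NW and 0.06 in SE against 2.97 in XM, where nearly all of clone 1 lay, and in lane BL of M30k it was -1.51. Its log2 fold change was 1.35 (SE 0.14, adjusted p = 0.0478). It was the 1 gene called of 15880 (edgeR with the mouse as a block), where 592 had an unadjusted p under 0.05. TNF (2.10, adjusted p = 0.329), the metallothionein gene MT1X (0.60, adjusted p = 0.777), CSF3 (3.60, adjusted p = 0.9) and ID2 (0.47, adjusted p = 0.9) had the next smallest p, did not pass, and had a positive log2 ratio in 4 of 4 mice. CSF3 averaged 0.0767 CPM in LL and 0.869 outside it, and TNF 0.281 and 1.46, so their ratios rest on few counts in the smaller sums. With 1 mouse left out edgeR called 0 genes, or 2 without M10k, and IL6 was not among them (372 to 891 at an unadjusted p under 0.05). Within 32 clones with at least 20 cells in both site classes, 317 genes were higher and 154 lower outside LL, and without the 16 clones of M5k these were 19 and 21. IL6 was left out there by the low-count filter. Clones of a mouse share its lanes, so these counts do not stand for 32 independent samples.

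NF-kB targets led the lists. Of 21, 20 had a positive log2 fold change (median 0.47), IL6 was called over all genes and 5 adjusted over the list alone (camera adjusted p = 6.62e-08, and adjusted p = 0.612 with an estimated correlation). NFKBIA had 0.49 and the chemokine gene CCL20 1.83, each positive in 4 of 4 mice (adjusted p = 1.00 for both). Immediate early genes had 16 of 19 positive and 4 called adjusted over the list alone, BTG2 (0.61) among them but not JUN (0.21). Their camera adjusted p was 7.3e-05, and 0.612 with an estimated correlation. ID and BMP feedback genes had 12 of 13 positive and 2 called adjusted over the list alone, ID2 (0.47) among them but not SKI (0.03). For this list the camera adjusted p was 0.0244, and 0.612 with an estimated correlation. In the other 6 lists called higher, 0 genes were called over all genes or adjusted over the list alone. These were G2/M genes (48 of 53 positive; CDC20 0.39, CDCA8 0.20; adjusted p = 9.1e-07) and cholesterol synthesis genes (20 of 20; adjusted p = 1.5e-06), each with adjusted p = 0.612 with an estimated correlation. Mesenchymal genes (14 of 17; ZEB2 0.84, FN1 0.39) and gastrointestinal genes (16 of 18; REG4 0.50, VIL1 0.07) each had an adjusted p of 0.00994, and adjusted p = 0.612 with an estimated correlation. FN1 and VIL1 were higher in 2 of 4 mice each, with their largest log2 ratios in M10k (2.06 and 0.93). REG4 went both ways, with a log2 ratio of -1.14 in M5k and 4.02 in M10k, and in M5k and M30k alone the gastrointestinal list was called lower (adjusted p = 0.0288). Keratins (9 of 10; KRT81 0.19, KRT80 0.04) had an adjusted p of 0.0224 and p53 targets (14 of 18; SESN2 0.15, PHLDA3 0.11) one of 0.028, both with adjusted p = 0.612 with an estimated correlation. PHLDA3 was also higher in 2 of 4 mice, with 0.87 in M10k.

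Lists lower outside LL were MHC class I genes (0 of 14 positive; HLA-F -0.25), interferon-stimulated genes (1 of 25 positive; ISG15 -0.42, IFI6 -0.19) and mitochondrially encoded genes (0 of 13 positive; MT-ND2 -0.21, MT-ND1 -0.18). The camera adjusted p were 1.86e-05, 1.86e-05 and 7.3e-07, and for each list adjusted p = 0.612 with an estimated correlation. Of their genes 0 were called over all genes, and 2 mitochondrial ones were lower adjusted over the list alone. The lanes differed in depth: in M5k the median UMI count per cell was 4957 in M1 and 4907 in M2 against 12604 in LL. Of the candidates, KRT17 (1.00), ID3 (0.26), ASPM (0.21), IFI27 (-0.32) and TNNT1 (-0.03) did not pass (adjusted p = 1.00 for each).

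**Figure D4:**
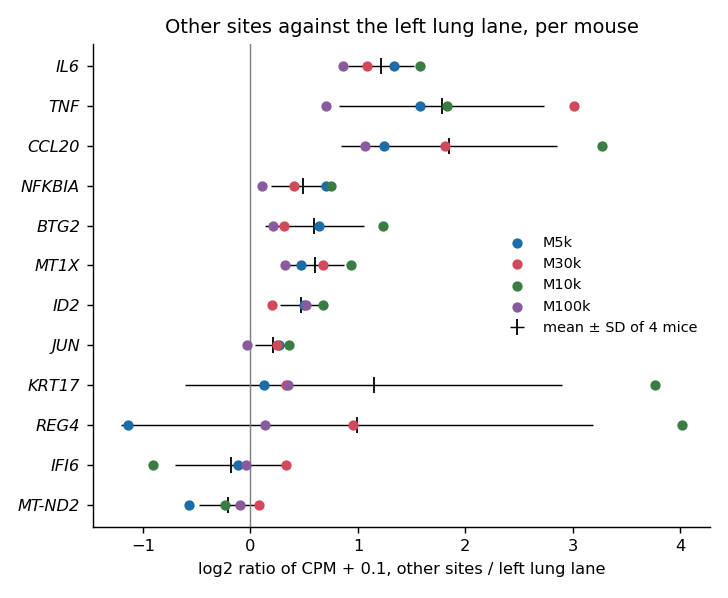
Log2 ratio of CPM + 0.1 at other sites to that in the LL lane (x axis) for genes of the site comparison, 1 point per mouse, with the mean and SD of 4 mice. IL6 lies between 0.86 and 1.58 in the 4 mice, whereas KRT17 is at 0.13 to 0.35 in 3 mice and at 3.77 in M10k.

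Clones of M5k with a higher tissue-crossing rate had more interferon and antigen presentation transcripts. Values here are log2 slopes for an increase of 1 SD in the rate (0.213) over 62 clones. REG4, a secreted lectin of gut epithelium (ENSG00000134193; GRCh38 chromosome 1, 119794018 to 119811660), rose by 0.77 (SE 0.17, adjusted p = 0.0087), from a mean of 39.0 CPM in the 21 clones with the lowest rates to 148 CPM in the 21 with the highest. The latter mean includes clone 16 at 972 CPM, whereas clones 53 and 41, also among these 21, were at 1.99 and 7.55 CPM. Clones 16, 18, 25 and 50, with at most 7.59% of cut sites edited, were also among these 21. Their rates may mostly follow the tissue mix. The protease inhibitor gene SERPINE2 rose by 0.62 (SE 0.13, adjusted p = 0.0049), from 56.1 to 154 CPM. The interferon-induced gene IFI27 rose by 0.59 (SE 0.11, adjusted p = 0.0013), from 81.2 to 189 CPM, a mean that includes clone 8 at 952 CPM. B2M, the light chain of MHC class I (ENSG00000166710; chromosome 15, 44711487 to 44718877), rose by 0.21 (SE 0.04, adjusted p = 0.0013), from 652 to 895 CPM. RSPO3, which amplifies Wnt signalling (ENSG00000146374; chromosome 6, 127118604 to 127197765), had a slope of -0.85 (SE 0.18, adjusted p = 0.0049) and went from 37.8 to 14.2 CPM.

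The test called 90 genes that rose and 54 that fell with the rate, of 8356 (edgeR). Other called rises were AC006262.5 (0.57), AGR3 (0.48), CLU (0.36), KRT15 (0.35), SLCO4A1 (0.33), IFI6 (0.32) and ISG15 (0.29). Other called falls were BICC1 (-0.54), C16orf74 (-0.49), FAM83A (-0.46), SPX (-0.44), NUAK2 (-0.38), CH17-360D5.2 (-0.34), C11orf96 (-0.33), SPECC1 (-0.30) and TNS1 (-0.28). The clones are separate founders in 1 animal, so these p-values cover clones of M5k and not mice. The count was 4 with the rate divided by its expected value, which takes out the tissue mix. For most of these genes, crossing can therefore not be told apart from the tissue mix of the clone. The count was also 4 with tissue dispersal, of which 0 were among the genes of the main fit, and 4 from cells of lane M1 alone.

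MHC class I genes rose with the rate: 11 of 11 were positive, 4 were called over all genes and 8 adjusted over the list alone (camera adjusted p = 1.43e-10). HLA-C had 0.26 and HLA-B 0.25. They are related genes, and whether they share counts was not tested. Of interferon-stimulated genes, 11 of 12 were positive, 4 were called over all genes, OAS3 (0.22) among them, and 5 adjusted over the list alone (adjusted p = 3.89e-06). Both lists were also called with an estimated correlation (adjusted p = 0.00861 for each). NF-kB targets were called lower, with 4 of 20 positive, 0 called over all genes, and 6 falls and 1 rise adjusted over the list alone (CXCL8 -0.26, TNFAIP3 -0.23, NFKBIA -0.18; adjusted p = 0.00127, and adjusted p = 0.602 with an estimated correlation). With dispersal and with the authors' dispersion in place of the rate the list was instead called higher (adjusted p = 3.42e-07 and 0.0352). G2/M genes were called lower with 4 of 20 positive and 0 genes called (SMC4 -0.10, LBR -0.09, ECT2 0.07; adjusted p = 0.0266, and adjusted p = 0.602 with an estimated correlation). Glycolysis genes were called higher, with 12 of 16 positive and 1 called both ways, the hexokinase gene HK2 (0.39; SLC2A1 0.08, PKM 0.08; adjusted p = 0.0189, and adjusted p = 0.602 with an estimated correlation). Hypoxia genes were called higher with 12 of 21 positive, HK2 again the 1 called and PFKFB4 at -0.15 (adjusted p = 0.0405, and adjusted p = 0.602 with an estimated correlation). From LL cells alone the hypoxia and glycolysis lists were instead called lower (adjusted p = 0.000109 and 0.000525). Invasion genes were called higher with 14 of 18 positive (camera adjusted p = 0.0405, and adjusted p = 0.602 with an estimated correlation). S100A4 (0.11) was called over all genes, and 2 genes, S100A4 included, adjusted over the list alone. TIMP1 had 0.15 and ITGA3 0.10. Of 7 candidates measured, REG4, IFI27 and IFI6 rose, while KRT17 (-0.44, adjusted p = 0.234), ID3 (-0.26, adjusted p = 0.19), TNNT1 (0.23, adjusted p = 0.249) and NFKBIA (adjusted p = 0.0518) did not pass.

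**Figure D5:**
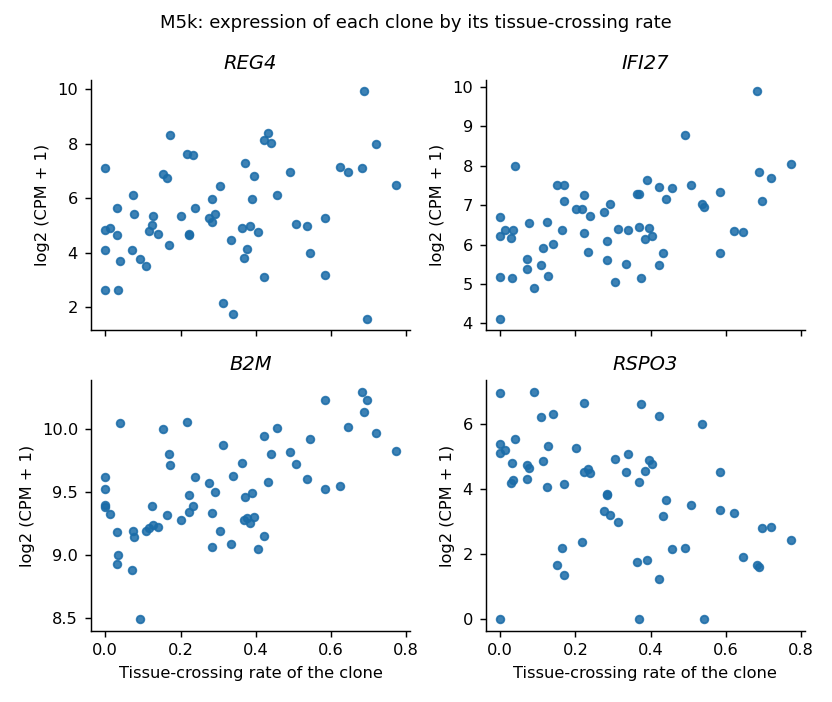
Expression, as log2 of CPM + 1, of 4 genes in each of the 62 clones of M5k (points) against the tissue-crossing rate of the clone. REG4, IFI27 and B2M rise with the rate (slopes 0.77, 0.59 and 0.21 per SD) and RSPO3 falls (-0.85).

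The direction of the 144 genes called in M5k was then read in the other 2 mice with at least 6 clones. In M100k, 115 of 135 measured genes had the same sign (85.2%), 23 were also called in the same direction and 0 in the opposite one. On log2 CPM the share was 83.0%, against a median of 50.4% for shuffled rates (permutation p = 0.0145, 14 clones). In M10k, 111 of 136 had the same sign (81.6%), and on log2 CPM 80.9% (permutation p = 0.0588, 10 clones). This rests on 1 clone: without clone 1 of M10k, whose rate is 0.0147, the share was 49.3% (permutation p = 0.519). Without the clone of M100k farthest from the median rate it was 85.2% (permutation p = 0.00554). Slopes of IFI27 were 1.16 in M100k (SE 0.27) and 1.96 in M10k (SE 0.47), the latter 1.69 (SE 0.98) without clone 1. RSPO3 had -1.26 in M100k (SE 0.47) and -1.08 in M10k (SE 0.36), or -2.27 (SE 1.22) without clone 1. In M100k, IFI6 had 0.16 (SE 0.15), ISG15 0.15 (SE 0.16), OAS3 0.02 (SE 0.11) and REG4 0.69 (SE 0.60). B2M had 0.28 there (SE 0.10), HLA-C 0.26 (SE 0.11) and HLA-B 0.25 (SE 0.13). In M10k without clone 1, B2M had -0.0051 (SE 0.34), HLA-C -0.24 (SE 0.37), HLA-B -0.30 (SE 0.42) and REG4 -1.07 (SE 2.12). IFI6 had 0.93 there (SE 0.52), ISG15 0.70 (SE 0.51) and OAS3 0.57 (SE 0.32).

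Clone numbers in the preimplantation annotation allowed clones to be compared before and after implantation. Of 8726 preimplantation cells, 731 (8.38%, 95% Wilson interval 7.81 to 8.98) were marked as engrafted in the authors' annotation, in 38 clones, and the largest 3 clones held 66.6% of them. Clones 15, 18 and 43 had at least 50 cells before implantation. By correlation across 1000 genes, which are not independent replicates, the M5k clone of the same number ranked 1, 2 and 2 of 100 (r = 0.332, 0.127 and 0.227). The mean r was 0.228 (one-sided permutation p = 1e-05, the smallest the resamples can give). The number of genes was chosen after runs with 100, 300 and 1000. With 300 genes the ranks were 1, 30 and 2 (permutation p = 0.00015), and with 100 genes 1, 29 and 2 (permutation p = 0.00034). The deposited tree rates of the preimplantation cells point to other clone numbers, and for 2 clones linked through them the mean r was -0.0319 (permutation p = 0.639).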

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

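Of the tests in this part, the depth covariate, the MHC list in single lanes, the within-clone NF-kB tests, the host marker test and the refits without clone 1 of M10k were chosen after the result was seen. In 98 groups of 4 mice, 6 had a mouse far from the other 3, where chance gives about 4.9. TargetSite libraries had a median of 150 UMIs per cell in M100k against 59 to 68 in the others. P4HA1 was at 77.8 CPM in M10k (62.1 to 63.8 in the others), MVK at 5.45 CPM in M5k (7.08 to 7.34) and NDUFS6 at 266 CPM in M100k (199 to 207). The log2 ratio of other sites to LL in M10k was 3.77 for KRT17 (0.13 to 0.35 in the others) and 0.67 for CDCA8 (-0.03 to 0.03).

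Slopes on the clone rate differed from those of M5k in 9 of 78 tests over the named genes (joint edgeR fit, adjusted over these tests). In M100k the slope of KRT15 was higher by 0.84 (adjusted p = 0.0346) and that of SLC2A1 lower, a difference of -0.44 (adjusted p = 0.012). In M10k the differences were 1.38 for IFI27, 1.44 for IFI6, 1.10 for ISG15, 0.43 for B2M, 0.29 for S100A4, -0.77 for CXCL8 and -0.74 for TNFAIP3 (adjusted p from 2.8e-05 to 0.0335). Without clone 1 of M10k, these 7 differences had unadjusted p from 0.176 to 0.837, with fewer clones and wider errors. IFI27 (1.11) and S100A4 (0.29) kept about their size, IFI6 (0.61) and ISG15 (0.41) shrank, and B2M (-0.21), CXCL8 (0.12) and TNFAIP3 (0.80) turned sign.

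The rise of MHC class I and interferon lists with the clone rate in M5k was weighed against technical sources. 1 of 100 assignments of the rates to the clones, the real one, called 144 genes, and the highest other called 4, so chance assignment is excluded for the gene count; camera however called at least 1 list in 93 of the 99 other assignments (median 4, at most 10), so its calls with the preset correlation are weak, although none reached the adjusted p of the MHC class I list (lowest 4.73e-05) or the interferon list (lowest 0.00332). Clone depth as the whole source is argued against, since with the median UMI count as a covariate both lists were still called (larger adjusted p = 3.43e-06). The lane mix of the clones stays open for both lists. Camera called the MHC class I list higher in lanes M1 and M2 each alone (larger adjusted p = 0.00416). This cannot decide it, since over all lanes a shuffled assignment called that list higher with a camera adjusted p of 0.00107. No shuffles were run within a lane. The interferon list was not called in M1 alone (camera adjusted p = 0.197), where fewer clones and genes keep it undecided. Whether the clones differed before implantation also stays open: over 10 clones the MHC class I level before and after had rho = 0.539 (permutation p = 0.112).

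The NF-kB list was higher outside LL. In the 6 lanes about as deep as the LL lane of their mouse, the median over lanes of its log2 ratio to LL was 0.103, with a standard error of 0.149 and lanes from -0.12 to 0.93, above the bound of 0.1 set beforehand by less than that error, so lane depth cannot be told apart from a difference between sites. The clone mix of the sites stays open: within clones the list was at 0.79 in M5k (15 of 16 clones above 0), 0.43 in M30k (2 of 2), 0.16 in M10k (2 of 4) and 0.07 in M100k (7 of 10), with a mean over mice of 0.362 (SE 0.161, 95% interval -0.15 to 0.87), so 4 mice are too few to decide, and the list's camera p over all 32 clones (adjusted p = 3.83e-09) does not decide it either, since clones of a mouse share its lanes. Lanes did not move alike: the ratio was above 0 in 12 of 20 lanes, at 1.83 in XM of M10k and -1.30 in BL of M30k, and tissue itself stays open as untested. For the count of genes in the site comparison, the 8 splits that part all 4 mice are too few for a share under 0.05; the real split called 1 gene and the highest other 0, while of 24 splits that part 2 mice 6 called at least as many, up to 5.

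Host hepatocyte and red cell lists were higher in the xenografts, for which RNA or cells of the host may be a source. The lowest median of the 5 host lists was -0.83, for the endothelial list, but this does not exclude it, because only 3 genes were measured, of which EGFL7, at 104 CPM before implantation, and ESAM, at 5.92 CPM and at most 0.298 CPM in the mice, were expressed by the line itself. HBB ranged from 3.46 to 903 CPM among the mice. ALB was at 0.141 CPM or less, below TTR (up to 16.1 CPM) and SERPINA1 (up to 11.2 CPM), and of the hepatocyte list AMBP (6.53 CPM) and APOH (8.27 CPM) were already expressed before implantation. How well mouse transcripts map to the human genes was not tested, which keeps a host source open.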

How the results depend on the processing

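Alternatives added after seeing the data are all barcodes, other gene table mice, pairs of mice, M5k or other clones alone, the authors' measures, depth and editing covariates, merged sites, single lanes M1 and M2, clones left out by size, every alternative of the before-and-after comparison, the direction of M5k genes without 1 clone, and dispersal against the divided rate; the causes of the shifts below were not tested unless stated.

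Xenograft against preimplantation called 120 genes. It called 383 without the low-count filter (more genes tested), 2384 by the DESeq2 Wald test, 3900 with the 2 mice sharing the preimplantation gene table, 5121 with the other 2, 207 with all barcodes, 0 from LL cells alone (edgeR; 2820 with an unadjusted p under 0.05), and 0 to 127 with 1 mouse left out (127 without M5k; 0 without M30k, M10k or M100k, with 2894, 3448 and 3391 at an unadjusted p under 0.05). Lists called fell from 15 to 0 with an estimated correlation, and the MHC class I list alone also lost its call without M10k and with the mice sharing the preimplantation gene table.

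Other sites against LL called 1 gene with the mouse as a block and 0 with no replicate block (edgeR; 28 with an unadjusted p under 0.05); 12 without the filter, 3 by DESeq2, 0 to 2 with 1 mouse left out (2 without M10k), 11 in M5k and M30k, 0 in M10k and M100k (478 with an unadjusted p under 0.05), 471 within clones, 2056 within clones of M5k and 40 within the other clones. 12 lists were called, 7 without the filter, 0 with an estimated correlation and 7 to 15 with 1 mouse left out (7 without M10k). The gastrointestinal list was called lower in M5k and M30k (adjusted p = 0.0288), and within clones of M5k REG4 was at -1.17 and PHLDA3 at -0.20. Of the named genes and called lists, IL6 and 4 lists (G2/M, gastrointestinal, ID and BMP feedback, p53) lost their call without the block.

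The clone rate called 144 genes: 262 without the filter, 292 with clones of at least 20 cells, 229 with merged sites, 87 in clones with an authors' rate, 36 from LL cells (17 clones), 4 from M1 cells, 28 from M2 cells, 11 with the authors' dispersion, 4 with dispersal and 4 with the rate divided by its expected value, all 4 of these last among the 144. Of 7 lists, 2 were called with an estimated correlation, 3 with at least 20 cells, 1 from M1 and 3 from M2 cells, and 4 each with the divided rate, the authors' rate, the authors' dispersion and merged sites. NF-kB targets were called higher with dispersal (adjusted p = 3.42e-07) and the authors' dispersion (0.0352), and hypoxia and glycolysis were called lower from LL cells (0.000109 and 0.000525). With dispersal the slopes of NUAK2, C11orf96 and HK2 turned to 0.0344, 0.0627 and -0.0231.

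The rate and clone size correlated in M5k with clones of at least 100 cells (r = 0.304, permutation p = 0.0448), but not by rank (rho = 0.293, permutation p = 0.054) or without 2 clones (r = 0.126, permutation p = 0.425). Correlations with dispersal were lost with the rate divided by its expected value in M5k (r = 0.0615) and M100k (r = 0.315). Median rates and dispersals stayed within 1 SD over clones under each alternative. Edited shares were 60.2%, 37.4% and 50.1% in M5k, M10k and M100k from molecules with at least 5 UMIs, and 53.1%, 71.2%, 38.3% and 35.9% in the 4 mice as means over clones. Linking clones before and after implantation by the tree rate gave a mean r of -0.0319. Without clone 1, M10k showed the same sign as M5k for 49.3% of genes. Among named genes of the clone comparison, 550 of the gene and setting pairs kept their side of the threshold, 169 no longer passed and 15 newly passed. For the xenografts these were 400, 97 and 97, and for the sites 368, 7 and 28. A gene called in neither fit counts as kept even where its sign turned. For the sites, where IL6 alone was called in the main fit, most kept pairs are of this uncalled kind. Depth limits the site comparison most in M30k, whose LL sum has 10339839 UMIs.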

Other observations

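The tests of clone expression before and after implantation were chosen after values had been seen; the test of shared founders was set before its result. Preimplantation cells marked as engrafted in the authors' annotation were compared with the other preimplantation cells over 18 gene lists. In this 1 library, with no replicates and with 66.6% of the marked cells in 3 clones, no test is given. The median log2 ratio of marked to other cells was 0.13 for G2/M genes (38 genes), 0.11 for S phase genes, 0.15 for epithelial genes, 0.11 for NRF2 targets, 0.12 for interferon-stimulated genes, 0.13 for ID and BMP feedback genes and 0.10 for immediate early genes. A median of 0 need not mark unchanged genes, since hypoxia genes, at 0.03, had a percentile of 54.0 among matched random lists. The ratio was -0.20 for p53 targets, -0.14 for mesenchymal genes and -0.13 for NF-kB targets, while MHC class I genes were at -0.01. REG4 had 0 counts in both sets of cells, and KRT17 5 counts among marked and 38 among other cells.

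M10k held a clone that barely left 1 lane. Clone 1 had 870 cells, 33.9% of the TargetSite cells of that mouse, a dispersal of 0.00347 and a tissue-crossing rate of 0.0147, and 0% of its cells lay in LL. Its expected rate was 0.0046, and 99 of 100 shuffles of its tissue labels were as low, so the low rate goes with its tissue mix. The lane XM, in which nearly all of them lay, had log2 ratios to LL of 2.97 for IL6, 1.83 for the NF-kB list and -0.97 for the MHC class I list. Since lane and clone coincide, they cannot be separated in these data.

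Clones may keep expression differences through implantation, a hypothesis formed on these data. Over the 10 clones with at least 10 preimplantation cells, the clone of the same number in M5k had a mean rank of 5.6 among 100 clones, with r above 0 in 10 of 10 (mean r = 0.152, permutation p = 1e-05, the smallest the resamples can give). For single lists this was not detectable over those 10 clones: rho was 0.539 for MHC class I (permutation p = 0.112), -0.152 for interferon-stimulated genes (p = 0.679, permutation) and 0.333 for NF-kB targets (p = 0.347, permutation). The reading depends on the clone numbers, because the deposited tree rates of the preimplantation cells point to other clones, for which the mean rank was 57.6 (8 clones, permutation p = 0.82). Clone sizes before and after had a Spearman rho of -0.0892, which was not tested.

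M10k and M100k may share founder clones, which would make them partly the same experiment. Clone 5 of M10k and clone 4 of M100k shared 11 of 11 target site integrations, and clone 4 ranked 1 of 31 in expression correlation with clone 5 (r = 0.657, next best 0.349). Clones 7 and 11 shared 7 integrations (rank 1, r = 0.646, next best 0.429), clones 11 and 16 shared 5 (rank 1, r = 0.627, next best 0.57), and clones 11 and 28 shared 5 (rank 6, r = 0.201). The first pair had rates of 0.653 in M10k and 0.509 in M100k, the second 0.773 and 0.533, the third 0.241 and 0, and the fourth 0.241 and 0.650.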
